A study of Arabidopsis thaliana with 45 samples.

How the data were processed

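RNA was taken from whole Arabidopsis seeds of the Col-0 background and sequenced as paired-end reads of 100 bases (DNBseq). The 45 libraries form 16 groups of 4 genotypes and 4 treatments, and the grouping follows the labels of each library. The deposited table holds estimated counts (expected counts) per transcript for 48268 transcripts. These counts come from Salmon per the submitters' processing notes, and its version, index and genome build are not given in the sources used here. Library totals were 18097331 to 22910834 counts. The values hold decimals and are not scaled for library size, as checked on the table. Estimated counts were summed over the transcripts of a locus and rounded, which gave 27587 loci. Gene names come from a table of reference gene names, which covers 27392 of these loci and was used for names alone, so no coordinates are given. A reference genome and its annotation were used only for length and GC content of the longest transcript of a locus. These were found for 99.4% of the tested loci and used for the qko replicate 7 libraries.

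Changes were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests. A single model held all 45 libraries with 1 coefficient for each of the 16 groups. Libraries were scaled with trimmed means (TMM). Loci with low counts were removed by group (minimum count 10, minimum total 15), which left 18066 loci and removed 9521. Adjusted p are Benjamini-Hochberg values within a comparison, and a gene changed where its adjusted p was under 0.05. The 27 comparisons are each treatment against its reference in each genotype, each mutant against WT in dry seeds and in water, and the difference between the response of a mutant and that of WT. The 9 main comparisons are the treatments in WT and each mutant against WT in dry seeds and in water. SE is that of the log2 fold change, taken from the F statistic, and SD is the spread of counts scaled to library size (CPM) between libraries. Fold bounds against a group at 0 use a floor of 3 counts per library and cover counting error only.

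Lists of genes, 21 in all with 341 genes of which 278 were tested, were fixed before the data were examined. So were the comparisons, the tests, the rule for named genes and the alternatives, except those said to be chosen later. Lists were tested against other genes with camera of limma 3.58.1 on log2 CPM (prior count 2), at a preset correlation between genes of 0.01 and again at an estimated one. Their p were adjusted over the lists of a comparison. Which list shifts hold with an estimated correlation is read from the p given beside each: the sulfur and defence lists in myb and qko, the detoxification list in myb in water, the breakdown and transport list in myb in water, and the nitrate list of cyp in KNO3. Medians of lists were computed also with genes that had a group at 0 counts set to their bound: among 85 list shifts past the threshold, 9 medians moved by more than 0.1 (log2). The largest move was 3.51, for the cell wall list from dry seeds to water in myb (4.74 to 1.23). Bounds were not computed for the differences in response.

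The rule for named genes takes, in each main comparison, up to 3 genes per list that passed with the largest change and a mean of at least 1 CPM, or the gene with the smallest p where none passed. It adds the 5 largest rises and 5 largest falls with at least 5 CPM and no overlap between libraries (for treatments in the mutants, the genes named for WT and up to 3 each way), and for the differences in response up to 3 genes each way. From these genes the text gives a part, chosen after their values were seen, and leaves out genes whose call changed without 1 library, except UPM1 in WT with KNO3. For a group under 3 counts per library the text gives CPM or a bound in place of a fold, except for the genes said to be of uncertain size. RFNR1 in WT and RFNR2 and NIA1 in cyp with KNO3 are outside the rule and were chosen after their values were seen. Among 18 genes the rule gave for the differences in response, 5 changed their call under another setting and 11 had a group under 3 counts per library, and the report draws on the remaining 7. For KNO3 and KSCN in the mutants the report gives the nitrate and the ribosomal protein list. This choice was made after the values of the other lists were seen, some of which passed at the preset correlation and none with an estimated one. The closing parts cover all 18 genes, all lists and the list differences that were lost without 1 library.

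Near-identical copies share reads, so the split between them is uncertain for SESA1 to SESA4, SOT17 and SOT18, NRT2.1 and its neighbour copy, IGMT1 and IGMT2, CYP79F1 and CYP79F2, TGG1 and TGG2, OPR1 and OPR2, GSTF6 and GSTF7, and the RBCS and LHCB1 genes.

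The replicate numbers in the labels were tested as pairs between treatments. In the libraries labelled qko the same number went together between KNO3 and water (correlations of residuals 0.338 to 0.562) and between KSCN and water (0.371 to 0.625). Replicate 7 lay apart in each imbibed qko group, which alone can give such correlations, so they do not show matched numbering. Between KNO3 and water not every qko library was closest to its own number. Between water and dry seeds the qko correlations were -0.041 to 0.00073. The rule asks for 3 shared numbers, and the KNO3 and KSCN comparisons in WT, cyp and myb shared at most 2, so none could pass. Their correlations ran from -0.078 (myb in KNO3) to 0.496 (cyp in KNO3). Over imbibed libraries of the same genotype, qko included, the mean was 0.266 for the same number and -0.092 for other numbers. Alternatives were size factors of the DESeq2 type, no filter on low counts, replicate number as a block, DESeq2 1.42.0, a model of the compared groups alone, and each library left out in turn. Total-count scaling, leaving out imbibed cyp replicate 8 or imbibed qko replicate 7, and a block within imbibed qko libraries were chosen after seeing the data. The procedure was tested on simulated data for 18066 genes, of which 17962 passed the filter again. Single genes and the 25 genes of the nitrate list were changed between WT in KNO3 and in water. The single genes had at least 5 CPM in WT in water and lay outside the lists. Each count was drawn on its own, so no simulated library stood apart. Of 67 genes changed 1.5-fold 38 were called, of 67 changed 2-fold 66, and of 66 changed 4-fold 66, while 18 of the 17841 unchanged genes simulated were called, 9.05% of all calls where the threshold aims at 5%. No gene was called for KSCN, where none was changed.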

Results

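Transcripts of Arabidopsis seeds were counted in 45 libraries from 4 genotypes and 4 treatments. The labels name the wild type (WT), a mutant of CYP79B2 and CYP79B3 (cyp), a mutant of MYB28 and MYB29 (myb), and a mutant of all 4 genes (qko). CYP79B2 and CYP79B3 make the precursor of indolic glucosinolates, and MYB28 and MYB29 switch on the synthesis of aliphatic glucosinolates. Seeds were dry, or were imbibed for 6 h in water, in 10 mM KNO3 or in 8 µM KSCN. Of the 16 groups, 13 held 3 libraries and 3 held 2 (cyp in KSCN, myb dry and myb in KNO3). Library totals ran from 18097331 to 22910834 counts. The lowest was replicate 7 of qko in KNO3, and the next lowest held 21363761. Of 27587 loci, 18066 had enough counts to be tested. The labels do not say whether replicates came from separate plants, so each p measures the spread between these samples.

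The first component of the tested genes held 53.5% of the variance and placed dry libraries apart from imbibed ones. The second component held 24.2% and ordered the imbibed libraries by genotype, with cyp and WT on the low side and myb and qko on the high side. Genotype also entered the first component, where the mean in water was 120 in cyp, 32.7 in WT, 30.0 in myb and 9.59 in qko. On the second, dry libraries had means of -65.0 in WT, -67.2 in cyp, -16.4 in myb and 2.69 in qko. Storage protein and oil body genes took 21.3% of the counts in dry WT seeds and 11.4% after 6 h in water. In the libraries labelled cyp these shares were 11.3% and 2.44%, in those labelled myb 16.3% and 6.89%, and in those labelled qko 14.7% and 5.12%. Imbibed libraries in KNO3 or KSCN lay with the water libraries of their own genotype. The imbibed cyp libraries of replicate 8 lay nearer to WT than the other imbibed cyp libraries. The imbibed qko libraries of replicate 7 lay apart from replicates 4 and 6 of their groups: in water the mean chi-square per gene was 75.5 and 76.3 against these, and 7.03 between replicates 4 and 6. Replicate 6 of WT in KNO3 also lay apart, at 25.9 and 27.2 against replicates 5 and 8 and 4.22 between those. In cyp in KNO3 the value between replicates 6 and 8 was 97.5.

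**Figure D1:**
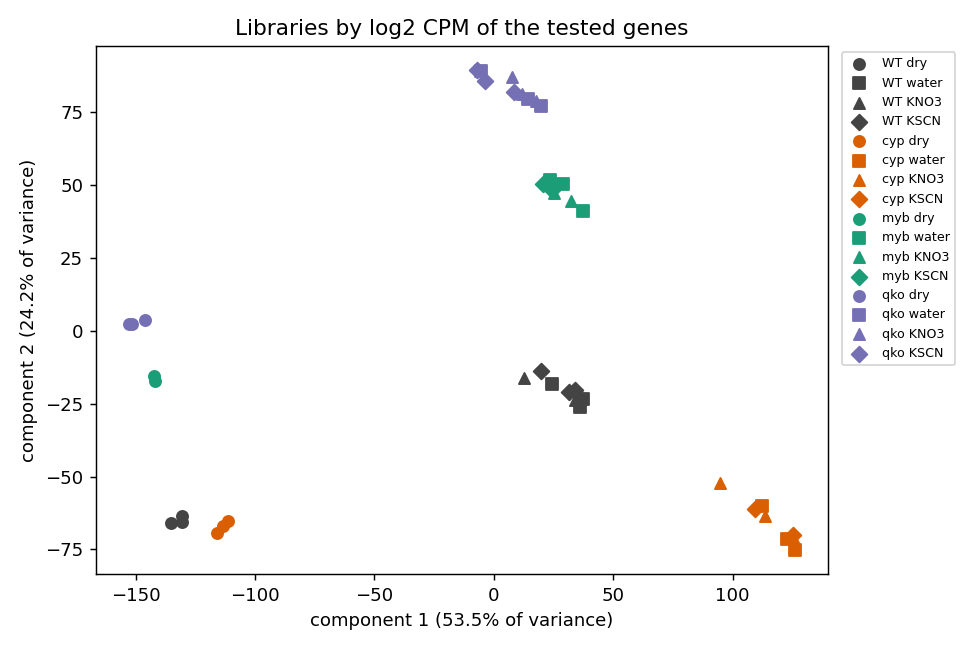
Each point is 1 library, placed by the first and second principal components of log2 CPM (percent of variance on the axes); colour gives the genotype label and shape the treatment. Dry and imbibed libraries parted along the first component (53.5%) and imbibed genotypes along the second (24.2%). Imbibed cyp libraries also lay apart on the first component, and dry myb and qko libraries on the second.

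Whether the targeted genes themselves differed came before any other comparison. MYB28 (AT5G61420) had 0 counts in all 45 libraries, WT included, so its mutation could not be read from these data. With 3 counts per library as the floor, this bounds it at 0.215 scaled counts (CPM) in dry WT seeds and 0.125 in WT seeds in water. MYB29 (AT5G07690) also had 0 counts in WT, in cyp and in all dry seeds. It was counted in imbibed myb and qko seeds, with at most 14 counts in a library. In water it reached 0.201 ± 0.0359 CPM (mean ± SD, n = 3) in myb, at least 1.60-fold higher than WT (adjusted p = 0.0086).

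CYP79B2 (AT4G39950) and CYP79B3 (AT2G22330) were higher, not lower, in the libraries labelled cyp. In dry seeds CYP79B2 stood at 1.46 ± 0.257 CPM in cyp and 0.119 ± 0.0824 in WT (adjusted p = 9.8e-04, n = 3 each), where WT lay under 3 counts per library. In water CYP79B3 stood at 3.47 ± 0.703 CPM in cyp and 0.180 ± 0.0455 in WT (log2 fold change 4.22, SE 0.45, adjusted p = 7.1e-10). In myb in water CYP79B2 stood at 0.334 ± 0.189 CPM (adjusted p = 0.028), where WT lay under 3 counts per library. In the libraries labelled qko CYP79B3 was also higher in water (log2 fold change 2.199, adjusted p = 7.4e-04), while CYP79B2 had 0 counts there and 3 in all WT water libraries together. A loss could hardly be read, because these genes lay at or near the floor in WT. MYB29 was counted only in imbibed libraries labelled myb and qko. In water CYP79B3 was highest in cyp, with 0.850 ± 0.264 CPM in qko. The transcripts thus differed with the labels, but do not show the losses that the labels name. Every direction below is that of the libraries labelled cyp, myb and qko, and transcript counts do not show whether a gene's product was lost.

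**Figure D2:**
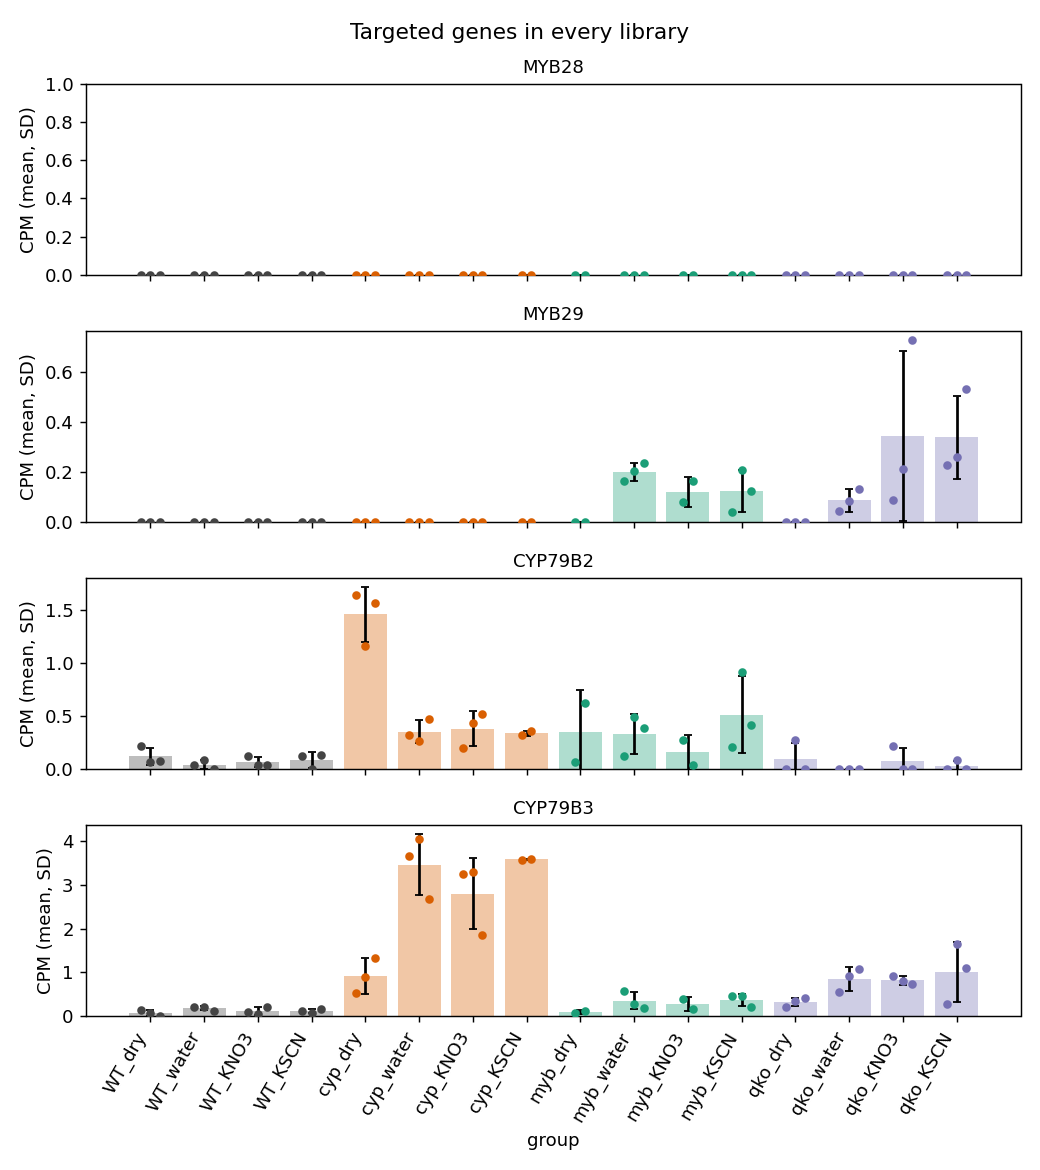
CPM of the targeted genes in every library (points) with the mean of each group and its SD (bars). MYB28 had 0 counts throughout, and CYP79B3 stood at 3.47 CPM in the water libraries labelled cyp and 0.180 in WT.

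What imbibition alone does to WT seeds was asked first. Relative to the trimmed-mean scaling, storage protein transcripts were lower after 6 h in water and transcripts of ribosome genes were higher. With total-count scaling the median over all genes rose by 0.75 (log2). The share of changed genes that were higher went from 52.6% to 82.5%. Sizes and counts of rises and falls in WT given here thus depend on the scaling. Some genes that loosen cell walls were higher, and a gibberellin-synthesis gene came up from 0 counts. Of the storage protein and oil body genes, 0 of 12 rose, 12 fell and 0 did not pass (adjusted over the list alone, 0 rose and 12 fell), among them CRU2 (AT1G03880, log2 fold change -1.92, SE 0.18, adjusted p = 1.2e-11) and CRU3 (AT4G28520, log2 fold change -1.74, SE 0.18, adjusted p = 1.4e-10). Of the cytosolic ribosomal protein genes, 20 of 20 rose, 0 fell and 0 did not pass (adjusted over the list alone, 20 rose and 0 fell), with RPS6A (AT4G31700) going from 64.0 ± 0.945 to 339.7 ± 54.9 CPM. Of the ribosome biogenesis genes, 8 of 9 rose, 0 fell and 1 did not pass (adjusted over the list alone, 8 rose and 0 fell), led by FIB2 (AT4G25630, log2 fold change 3.04, SE 0.18, adjusted p = 1.2e-16), a fibrillarin of the nucleolus. Of the cell wall loosening genes, 6 of 10 rose, 0 fell and 4 did not pass (adjusted over the list alone, 6 rose and 0 fell). The expansin EXPA1 (AT1G69530) went from 0.0959 ± 0.0831 to 73.1 ± 16.7 CPM, and EXPA10 (AT1G26770, log2 fold change 7.58, SE 0.25, adjusted p = 1.7e-23) rose too.

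These 4 lists shifted against all other genes by camera at a preset correlation of 0.01. The storage list gave a median log2 fold change -1.63, adjusted p = 2.6e-04, and adjusted p = 0.58 with an estimated correlation. The ribosomal protein list gave a median log2 fold change 1.05, adjusted p = 6.4e-05, and adjusted p = 0.58 with an estimated correlation. The ribosome biogenesis list gave a median log2 fold change 1.64, adjusted p = 6.2e-04, and adjusted p = 0.58 with an estimated correlation. The cell wall list gave a median log2 fold change 2.78, adjusted p = 0.0082, and adjusted p = 0.58 with an estimated correlation, and its median was 1.89 with genes that had a group at 0 counts set to their bound. The cell wall shift was lost with total-count scaling (adjusted p = 0.10). GA3OX2 (AT1G80340), which makes active gibberellin, was at 0 counts in dry seeds and at least 30.6-fold higher in water. The transcription factor gene bZIP44 (AT1G75390) was at least 119.9-fold higher, and VGD1 (AT2G47040), a pollen pectin methylesterase gene, was at least 85.4-fold lower.

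Nitrogen and sulfur genes moved in both directions in WT seeds in water. Of the nitrate genes, 18 of 25 rose, 5 fell and 2 did not pass (adjusted over the list alone, 18 rose and 5 fell). The nitrate reductase genes NIA1 (AT1G77760, log2 fold change 3.88, SE 0.35, adjusted p = 4.9e-12) and NIA2 (AT1G37130, log2 fold change 3.302, SE 0.30, adjusted p = 7.0e-12) rose, and asparagine synthetase ASN1 (AT3G47340, log2 fold change -2.23, SE 0.20, adjusted p = 2.9e-12) fell. Of the sulfur genes, 15 of 25 rose, 8 fell and 2 did not pass (adjusted over the list alone, 15 rose and 8 fell), with LSU2 (AT5G24660, log2 fold change 3.88, SE 0.30, adjusted p = 1.2e-13), a marker of sulfur shortage, among those that rose. Of the abscisic acid (ABA) genes, 9 of 29 rose, 18 fell and 2 did not pass (adjusted over the list alone, 9 rose and 18 fell). ABI4 (AT2G40220) went from 2.90 ± 0.511 to 82.3 ± 4.42 CPM. Of the gibberellin genes, 14 of 25 rose, 9 fell and 2 did not pass (adjusted over the list alone, 14 rose and 9 fell). Of the late embryogenesis (LEA), dormancy and heat shock genes, 2 of 12 rose, 7 fell and 3 did not pass (adjusted over the list alone, 2 rose and 7 fell), and the seed heat shock factor HSFA9 (AT5G54070, log2 fold change -3.15, SE 0.31, adjusted p = 2.8e-11) fell. None of these 5 lists shifted against other genes (adjusted p = 0.082, 0.2, 0.065, 0.095 and 0.095).

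Other lists did not shift either. Of the aliphatic glucosinolate synthesis genes, 3 of 10 rose, 0 fell and 7 did not pass (adjusted over the list alone, 3 rose and 0 fell), and of the indolic ones, 7 of 14 rose, 1 fell and 6 did not pass (adjusted over the list alone, 7 rose and 1 fell). The aliphatic genes MAM1, MAM3, CYP79F1 and CYP79F2 had 0 counts in all libraries and were not tested. Of the glucosinolate regulators, 3 of 6 rose, 2 fell and 1 did not pass (adjusted over the list alone, 3 rose and 2 fell), and of the genes for glucosinolate breakdown and transport, 3 of 13 rose, 6 fell and 4 did not pass (adjusted over the list alone, 3 rose and 6 fell). NSP2 (AT2G33070), which directs glucosinolate breakdown in seeds, fell from 5225 ± 246 to 1310.2 ± 39.8 CPM. Of the ammonium genes, 4 of 10 rose, 2 fell and 4 did not pass (adjusted over the list alone, 4 rose and 2 fell). Of the cyanide and thiocyanate genes, 4 of 8 rose, 2 fell and 2 did not pass (adjusted over the list alone, 4 rose and 2 fell). Of the lipid mobilisation genes, 4 of 11 rose, 1 fell and 6 did not pass (adjusted over the list alone, 4 rose and 0 fell), and of the auxin genes, 5 of 10 rose, 3 fell and 2 did not pass (adjusted over the list alone, 5 rose and 3 fell). Of the defence genes, 1 of 6 rose, 2 fell and 3 did not pass (adjusted over the list alone, 1 rose and 2 fell), and of the detoxification genes, 8 of 15 rose, 3 fell and 4 did not pass (adjusted over the list alone, 8 rose and 3 fell). Of the seed coat markers, 1 of 5 rose, 0 fell and 4 did not pass (adjusted over the list alone, 1 rose and 0 fell), and of the photosynthesis markers, 1 of 4 rose, 3 fell and 0 did not pass (adjusted over the list alone, 1 rose and 3 fell). In total 12757 genes changed at an adjusted p under 0.05, 6710 higher and 6047 lower.

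Whether imbibition differed in the mutants was then read from the same comparison in each. In water against dry seeds 14405 genes changed in cyp, 11952 in myb and 12474 in qko. These counts stayed within 1.5 times their value with total-count scaling, but the share that were higher did not stay the same. With that scaling the median over all genes rose by 0.75 (log2) in WT, 0.74 in cyp, 0.68 in myb and 0.72 in qko. The share of changed genes that were higher went from 52.6% to 82.5% in WT, from 51.2% to 72.6% in cyp, from 52.6% to 81.2% in myb and from 53.4% to 81.8% in qko. Changes are given relative to the trimmed-mean scaling. Storage protein genes fell in all mutants: in cyp 12 of 12 (median -3.003), in myb 12 (median -1.77) and in qko 12 (median -2.04). Ribosomal protein genes rose in number from 11 of 20 in qko to 19 in myb and 20 in cyp.

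What nitrate does to WT seeds was asked by comparing KNO3 with water. The list of nitrate transport, assimilation and primary response shifted up by a small amount at the preset correlation and not with an estimated one, and no gene passed over all genes tested. The largest support was for UPM1 (AT5G40850), which makes the sirohaem of nitrite reductase, at 219 ± 14.3 CPM in KNO3 and 154 ± 6.10 in water (log2 fold change 0.50, SE 0.09, adjusted p = 0.066, n = 3 each). UPM1 passed with the replicate block (adjusted p = 0.037), with total-count scaling (0.041), by DESeq2 (1.7e-04) and without replicate 5 of WT in KNO3 (0.047). Of the nitrate list 0 of 25 genes rose over all genes tested, and adjusted over the list alone 2 rose, UPM1 and RFNR1 (AT4G05390). The list as a whole shifted up (median log2 fold change 0.29, adjusted p = 2.7e-11, and adjusted p = 0.19 with an estimated correlation). By edgeR 0 genes changed, with 366 at an unadjusted p under 0.05 and 2 by DESeq2. Without replicate 5 of WT in KNO3, 2 genes changed. The lipid mobilisation list shifted down (median log2 fold change -0.10, adjusted p = 0.033, and adjusted p = 0.89 with an estimated correlation), and this was lost without replicate 5 of WT in water (adjusted p = 0.25) or replicate 6 of WT in KNO3 (adjusted p = 0.66). On simulated data with 3 libraries in each group, 38 of 67 genes changed 1.5-fold and 66 of 67 changed 2-fold were recovered. These genes had at least 5 CPM in WT in water, so changes under 1.5-fold were often not detectable even there. No single gene of fewer counts was changed, and no simulated library stood apart as replicate 6 of WT in KNO3 does.

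What thiocyanate does to WT seeds was asked by comparing KSCN with water. No gene passed over all genes tested. TGG1 (AT5G26000), a myrosinase that cleaves glucosinolates, stood at 63.8 ± 16.8 CPM in KSCN and 87.7 ± 4.68 in water (adjusted p = 1.0). CYSC1 (AT3G61440), which detoxifies cyanide, stood at 24.1 ± 0.235 and 27.9 ± 5.70 CPM (adjusted p = 1.0). The ribosomal protein list shifted down (median log2 fold change -0.10, adjusted p = 0.0094, and adjusted p = 0.94 with an estimated correlation) and the detoxification list up (median log2 fold change 0.13, adjusted p = 0.037, and adjusted p = 0.94 with an estimated correlation). The ribosomal shift was lost without replicate 5 or 8 of WT in water (adjusted p = 0.16 and 0.83) or replicate 8 of WT in KSCN (adjusted p = 0.11). The detoxification shift was lost without the same libraries (adjusted p = 0.43, 0.18 and 0.90). By edgeR 0 genes changed, with 173 at an unadjusted p under 0.05 and 0 by DESeq2.

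The dry seeds labelled cyp were compared with dry WT seeds to ask what differs before imbibition. They held fewer transcripts of storage proteins, of the dormancy gene DOG1 and of the myrosinase gene TGG1. Transcripts of NIT4, a nitrilase that acts on the product of cyanide detoxification, were higher. Of the storage protein and oil body genes, 0 of 12 rose, 11 fell and 1 did not pass (adjusted over the list alone, 0 rose and 11 fell), with SESA3 (AT4G27160, log2 fold change -2.66, SE 0.27, adjusted p = 2.0e-09) and ATS1 (AT4G26740, log2 fold change -1.71, SE 0.18, adjusted p = 4.0e-09). The storage list gave a median log2 fold change -1.15, adjusted p = 9.3e-10, and adjusted p = 0.19 with an estimated correlation. NIT4 (AT5G22300) stood at 8.99 ± 0.733 CPM in cyp and 0.624 ± 0.228 in WT (n = 3 each). Of the cyanide and thiocyanate genes, 4 of 8 rose, 1 fell and 3 did not pass (adjusted over the list alone, 5 rose and 1 fell). That list gave a median log2 fold change 0.97, adjusted p = 0.044, and adjusted p = 0.21 with an estimated correlation, with a median of 0.52 where a gene with a group at 0 counts was set to its bound. It was lost without replicate 5 or 8 of dry WT (adjusted p = 0.072 and 0.064) or replicate 8 of dry cyp (adjusted p = 0.084).

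Single genes of the dry cyp seeds showed larger differences. DOG1 (AT5G45830, log2 fold change -1.81, SE 0.16, adjusted p = 1.3e-10) and TGG1 (AT5G26000, log2 fold change -2.25, SE 0.25, adjusted p = 1.6e-08) fell. So did MRD1 (AT1G53480), at 0.383 ± 0.0551 CPM in cyp and 14.1 ± 1.59 in WT, and VIM2 (AT1G66050, log2 fold change -3.55, SE 0.18, adjusted p = 2.2e-16), which binds methylated DNA. Among nitrate genes LBD39 (AT4G37540, log2 fold change -3.37, SE 0.42, adjusted p = 1.8e-07) fell and NIA1 (log2 fold change 1.46, SE 0.33, adjusted p = 9.9e-04) rose. In total 5319 genes changed, 2904 higher and 2415 lower. The count was 9211 with total-count scaling and 8044 when the model held only the groups compared. With total-count scaling the median over all genes rose by 0.38 (log2) and the share that were higher went from 54.6% to 93.9%. Of the aliphatic glucosinolate genes 1 rose and 2 fell, and of the indolic genes 4 rose and 1 fell. Neither list shifted among its tested genes (adjusted p = 0.74 and 0.13).

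Seeds labelled cyp and WT were compared after imbibition in water to ask how they differ once imbibed. Storage, LEA and heat shock transcripts were low, ABA and sulfur genes were mostly lower, and gibberellin, cell wall and ribosome genes were mostly higher. Of the storage genes, 0 of 12 rose, 12 fell and 0 did not pass (adjusted over the list alone, 0 rose and 12 fell). OLEO4 (AT3G27660), an oil body protein gene, stood at 296 ± 90.6 CPM in cyp and 3548 ± 92.7 in WT. Of the LEA, dormancy and heat shock genes, 0 of 12 rose, 12 fell and 0 did not pass (adjusted over the list alone, 0 rose and 12 fell), with HSFA9 (log2 fold change -4.08, SE 0.34, adjusted p = 2.5e-12) and HSP101 (AT1G74310, log2 fold change -3.98, SE 0.31, adjusted p = 2.5e-13). Of the ABA genes, 4 of 29 rose, 20 fell and 5 did not pass (adjusted over the list alone, 4 rose and 20 fell). RAB18 (AT5G66400, log2 fold change -3.37, SE 0.25, adjusted p = 1.3e-13), an ABA-induced dehydrin, went from 14861 CPM in WT to 1439.6. Of the sulfur genes, 2 of 25 rose, 18 fell and 5 did not pass (adjusted over the list alone, 2 rose and 19 fell), with APR2 (AT1G62180, log2 fold change -2.01, SE 0.17, adjusted p = 3.4e-12), which reduces sulfate, among those that fell.

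Most gibberellin, cell wall and ribosome genes were higher in the water libraries labelled cyp. Of the gibberellin genes, 18 of 25 rose, 3 fell and 4 did not pass (adjusted over the list alone, 18 rose and 3 fell), with GA3OX2 (AT1G80340, log2 fold change 3.03, SE 0.38, adjusted p = 3.9e-08) and GASA6 (AT1G74670, log2 fold change 3.78, SE 0.50, adjusted p = 1.0e-07). Of the cell wall loosening genes, 8 of 10 rose, 1 fell and 1 did not pass (adjusted over the list alone, 8 rose and 2 fell). EXPA2 (AT5G05290) stood at 370.4 ± 107 CPM in cyp and 12.6 ± 7.93 in WT, and EXPA1 at 819 ± 195 and 73.1 ± 16.7. Of the ribosomal protein genes, 19 of 20 rose, 0 fell and 1 did not pass (adjusted over the list alone, 19 rose and 0 fell), and of the ribosome biogenesis genes, 9 of 9 rose, 0 fell and 0 did not pass (adjusted over the list alone, 9 rose and 0 fell). Of the indolic glucosinolate genes, 10 of 14 rose, 2 fell and 2 did not pass (adjusted over the list alone, 10 rose and 2 fell), with CYP83B1 (AT4G31500, log2 fold change 2.75, SE 0.30, adjusted p = 8.2e-10), the step after CYP79B2 and CYP79B3. Of the cyanide and thiocyanate genes, 6 of 8 rose, 1 fell and 1 did not pass (adjusted over the list alone, 7 rose and 1 fell), with CYSC1 (AT3G61440, log2 fold change 2.14, SE 0.25, adjusted p = 5.9e-09). Of the detoxification genes, 1 of 15 rose, 10 fell and 4 did not pass (adjusted over the list alone, 1 rose and 10 fell). Of the photosynthesis markers, 2 of 4 rose, 0 fell and 2 did not pass (adjusted over the list alone, 2 rose and 0 fell), with a median of 1.65, and of the seed coat markers, 0 of 5 rose, 3 fell and 2 did not pass (adjusted over the list alone, 0 rose and 4 fell), with a median of -0.93. Neither of these marker lists shifted against other genes (adjusted p = 0.085 and 0.46).

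These 11 lists shifted in the water libraries labelled cyp at the preset correlation, and none did with an estimated correlation. For storage the shift was a median log2 fold change -2.55, adjusted p = 9.1e-09, and adjusted p = 0.095 with an estimated correlation. For LEA, dormancy and heat shock it was a median log2 fold change -2.97, adjusted p = 1.0e-08, and adjusted p = 0.095 with an estimated correlation. For ABA it was a median log2 fold change -0.86, adjusted p = 5.5e-05, and adjusted p = 0.095 with an estimated correlation, and for sulfur a median log2 fold change -0.87, adjusted p = 6.2e-04, and adjusted p = 0.095 with an estimated correlation. For gibberellin it was a median log2 fold change 0.90, adjusted p = 7.9e-04, and adjusted p = 0.095 with an estimated correlation, and for the cell wall a median log2 fold change 2.01, adjusted p = 0.0028, and adjusted p = 0.095 with an estimated correlation. The cell wall median was 1.77 with bounds for genes with a group at 0 counts. For ribosomal proteins it was a median log2 fold change 0.81, adjusted p = 6.0e-06, and adjusted p = 0.29 with an estimated correlation, and for ribosome biogenesis a median log2 fold change 0.62, adjusted p = 9.5e-04, and adjusted p = 0.29 with an estimated correlation. For indolic glucosinolates it was a median log2 fold change 1.79, adjusted p = 0.027, and adjusted p = 0.15 with an estimated correlation, lost with total-count scaling (adjusted p = 0.11). For cyanide and thiocyanate it was a median log2 fold change 0.77, adjusted p = 0.029, and adjusted p = 0.19 with an estimated correlation, and for detoxification a median log2 fold change -1.06, adjusted p = 0.021, and adjusted p = 0.31 with an estimated correlation. In total 11398 genes changed, 5631 higher and 5767 lower. With total-count scaling the median over all genes rose by 0.36 (log2) and the share that were higher went from 49.4% to 72.5%.

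The libraries labelled myb and qko were compared with WT in dry seeds to ask what differs before imbibition. Sulfur genes were mostly higher and transcripts of the myrosinase gene TGG1 were nearly gone. Most tested genes of the camalexin, jasmonate and salicylate list, mainly jasmonate genes, were higher, and most storage protein genes were lower. Of the sulfur genes, 16 of 25 rose, 6 fell and 3 did not pass (adjusted over the list alone, 17 rose and 7 fell) in myb, and 18 of 25 rose, 5 fell and 2 did not pass (adjusted over the list alone, 18 rose and 5 fell) in qko. LSU1 (AT3G49580), induced by sulfur shortage, stood at 96.0 ± 15.1 CPM in myb (n = 2), 178 ± 28.9 in qko (n = 3) and 0.238 ± 0.163 in WT (n = 3). BGLU28 (AT2G44460), a glucosidase induced by sulfur shortage, stood at 183 ± 3.72, 449 ± 62.5 and 0.357 ± 0.308 CPM. TGG1 stood at 1.04 ± 0.498, 0.373 ± 0.0348 and 235 ± 26.9 CPM. The sulfur list gave a median log2 fold change 2.097, adjusted p = 1.5e-05, and adjusted p = 0.047 with an estimated correlation in myb and a median log2 fold change 2.55, adjusted p = 5.2e-07, and adjusted p = 0.017 with an estimated correlation in qko, where the median was 2.39 with bounds.

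Defence and nitrogen genes differed too in the dry seeds labelled myb and qko. Of the camalexin, jasmonate and salicylate genes, 5 of 6 rose, 0 fell and 1 did not pass (adjusted over the list alone, 5 rose and 0 fell) in myb, and 5 of 6 rose, 0 fell and 1 did not pass (adjusted over the list alone, 5 rose and 0 fell) in qko. The highest counts in a library were 1564 for JAZ1, 924 for JAZ10 and 824 for AOS, but 30 for CYP71A13 and 13 each for LOX2 and PR1. The camalexin and salicylate parts thus rest on CYP71A13 and PR1, which had few counts. The jasmonate repressor JAZ1 (AT1G19180, log2 fold change 3.42, SE 0.15, adjusted p = 7.2e-20) and the jasmonate synthesis gene AOS (AT5G42650, log2 fold change 3.31, SE 0.23, adjusted p = 7.0e-14) rose in myb, and JAZ1 rose in qko by 4.02 (log2, SE 0.14). That list gave a median log2 fold change 3.09, adjusted p = 2.2e-04, and adjusted p = 0.01 with an estimated correlation in myb and a median log2 fold change 3.34, adjusted p = 2.9e-04, and adjusted p = 0.012 with an estimated correlation in qko (medians 2.44 and 2.47 with bounds). Of the nitrate genes, 3 of 25 rose, 12 fell and 10 did not pass (adjusted over the list alone, 3 rose and 13 fell) in myb, with NRT3.1 (AT5G50200, log2 fold change -2.30, SE 0.44, adjusted p = 6.5e-05) and NIR1 (AT2G15620, log2 fold change -2.14, SE 0.37, adjusted p = 1.4e-05) among those that fell. The nitrate list gave a median log2 fold change -0.50, adjusted p = 0.011, and adjusted p = 0.76 with an estimated correlation in myb. In qko, 5 of 25 rose, 11 fell and 9 did not pass (adjusted over the list alone, 5 rose and 11 fell), and the list did not shift (adjusted p = 0.089), with NIA1 (log2 fold change -4.06, SE 0.50, adjusted p = 1.8e-08) among those that fell. GDH2 (AT5G07440, log2 fold change 2.49, SE 0.22, adjusted p = 1.0e-11), a glutamate dehydrogenase gene, rose in qko.

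Stores differed as well in the dry seeds labelled myb and qko. Of the storage genes, 0 of 12 rose, 9 fell and 3 did not pass (adjusted over the list alone, 1 rose and 9 fell) in myb, and 1 of 12 rose, 9 fell and 2 did not pass (adjusted over the list alone, 1 rose and 9 fell) in qko. CRU2, a cruciferin gene, stood at 1005 ± 2.61 CPM in myb, 989 ± 166 in qko and 12437 ± 784 in WT. The storage list gave a median log2 fold change -0.94, adjusted p = 1.2e-04, and adjusted p = 0.55 with an estimated correlation in myb and a median log2 fold change -1.26, adjusted p = 6.5e-05, and adjusted p = 0.41 with an estimated correlation in qko. The list of glucosinolate breakdown and transport gave a median log2 fold change 1.61, adjusted p = 0.0025, and adjusted p = 0.12 with an estimated correlation in myb and a median log2 fold change 1.31, adjusted p = 0.011, and adjusted p = 0.26 with an estimated correlation in qko. In qko, 8 of 11 rose, 0 fell and 3 did not pass (adjusted over the list alone, 8 rose and 0 fell) among the lipid mobilisation genes (median log2 fold change 0.86, adjusted p = 7.7e-04, and adjusted p = 0.63 with an estimated correlation). DOG1 (log2 fold change -2.29, SE 0.19, adjusted p = 7.3e-12) fell in myb. The detoxification list rose in qko (median log2 fold change 0.91, adjusted p = 0.049, and adjusted p = 0.74 with an estimated correlation), and this was lost without replicate 5 or 8 of dry WT (adjusted p = 0.064 and 0.079) or replicate 4 or 6 of dry qko (adjusted p = 0.073 and 0.054). Neither glucosinolate synthesis list shifted among its tested genes: for the aliphatic list adjusted p = 0.68 in myb and 0.83 in qko, and for the indolic list 0.56 and 0.58. MAM1, MAM3, CYP79F1 and CYP79F2 of the aliphatic list had 0 counts in all libraries, WT included, and BCAT4 at most 1. The test covers the 10 other genes counted well enough and cannot show a change in these. In total 6857 genes changed in myb and 8844 in qko. With total-count scaling the median over all genes rose by 0.13 (log2) in myb and the share that were higher went from 54.4% to 69.5%.

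In water the sulfur and detoxification genes were mostly higher in the libraries labelled myb and qko than in WT, and storage genes were mostly lower. The tested genes of the camalexin, jasmonate and salicylate list, mainly jasmonate genes, were mostly higher too. Of the sulfur genes, 16 of 25 rose, 3 fell and 6 did not pass (adjusted over the list alone, 16 rose and 3 fell) in myb, and 18 of 25 rose, 3 fell and 4 did not pass (adjusted over the list alone, 18 rose and 3 fell) in qko. LSU1 stood at 260.2 ± 46.5 CPM in myb, 399.9 ± 170.3 in qko and 1.25 ± 0.283 in WT (n = 3 each). GGCT2;1 (AT5G26220, log2 fold change 6.78, SE 0.25, adjusted p = 7.4e-21), which recycles glutathione, and BGLU30 (AT3G60140, log2 fold change 5.55, SE 0.26, adjusted p = 1.2e-18) rose in myb. TGG1 (log2 fold change -6.71, SE 0.36, adjusted p = 3.8e-17) fell in myb, and TGG1 stood at 0.0565 ± 0.0489 CPM in qko, under 3 counts per library, and 87.7 ± 4.68 in WT. Of the detoxification genes, 14 of 15 rose, 0 fell and 1 did not pass (adjusted over the list alone, 14 rose and 0 fell) in myb, and 12 of 15 rose, 0 fell and 3 did not pass (adjusted over the list alone, 14 rose and 0 fell) in qko. UGT73B5 (AT2G15480, log2 fold change 4.11, SE 0.41, adjusted p = 1.6e-10) and OPR1 (AT1G76680, log2 fold change 3.96, SE 0.23, adjusted p = 2.1e-16), induced by reactive electrophiles, rose in qko. Of the defence list, 5 of 6 rose, 0 fell and 1 did not pass (adjusted over the list alone, 6 rose and 0 fell) in myb, and 6 of 6 rose, 0 fell and 0 did not pass (adjusted over the list alone, 6 rose and 0 fell) in qko, with AOS (log2 fold change 3.27, SE 0.23, adjusted p = 8.0e-14) in myb.

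These lists shifted as follows in water. The sulfur list gave a median log2 fold change 1.62, adjusted p = 1.8e-10, and adjusted p = 0.0021 with an estimated correlation in myb, and a median log2 fold change 2.08, adjusted p = 1.1e-09, and adjusted p = 0.0067 with an estimated correlation in qko. The detoxification list gave a median log2 fold change 1.48, adjusted p = 2.2e-08, and adjusted p = 0.038 with an estimated correlation in myb, and a median log2 fold change 1.74, adjusted p = 5.5e-08, and adjusted p = 0.065 with an estimated correlation in qko. The defence list gave a median log2 fold change 2.99, adjusted p = 3.7e-06, and adjusted p = 0.0013 with an estimated correlation in myb, and a median log2 fold change 2.79, adjusted p = 4.0e-04, and adjusted p = 0.0085 with an estimated correlation in qko. The breakdown and transport list gave a median log2 fold change 1.90, adjusted p = 1.5e-05, and adjusted p = 0.015 with an estimated correlation in myb, and a median log2 fold change 0.83, adjusted p = 0.013, and adjusted p = 0.19 with an estimated correlation in qko. The storage list gave a median log2 fold change -1.18, adjusted p = 4.0e-08, and adjusted p = 0.12 with an estimated correlation in myb, and a median log2 fold change -1.69, adjusted p = 5.5e-08, and adjusted p = 0.19 with an estimated correlation in qko. Marker lists did not shift in either mutant. In water the seed coat median was -1.37 in myb (adjusted p = 0.22) and -0.25 in qko (0.72), and the photosynthesis median -0.05 (0.69) and -0.79 (0.43). In dry seeds these were -0.84 (0.52) and -0.49 (0.81), and -0.76 (0.42) and -1.001 (0.34).

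Gibberellin and ribosome biogenesis genes were mostly lower in the water libraries labelled qko, of which replicate 7 lay apart. Of the nitrate genes, 6 of 25 rose, 10 fell and 9 did not pass (adjusted over the list alone, 6 rose and 10 fell), and the list did not shift (adjusted p = 0.36). NIA2 (log2 fold change -3.48, SE 0.29, adjusted p = 3.8e-12) and NRT3.1 (log2 fold change -3.06, SE 0.32, adjusted p = 5.8e-10) fell, and GDH2 (log2 fold change 3.39, SE 0.23, adjusted p = 7.7e-15) rose. Of the gibberellin genes, 2 of 25 rose, 13 fell and 10 did not pass (adjusted over the list alone, 2 rose and 13 fell) (median log2 fold change -0.31, adjusted p = 0.01, and adjusted p = 0.21 with an estimated correlation), with GA20OX2 (AT5G51810, log2 fold change -3.31, SE 0.31, adjusted p = 4.8e-11) among those that fell. Of the ribosome biogenesis genes, 1 of 9 rose, 8 fell and 0 did not pass (adjusted over the list alone, 1 rose and 8 fell) (median log2 fold change -0.47, adjusted p = 0.019, and adjusted p = 0.71 with an estimated correlation). That shift was lost without replicate 7 of qko in water (adjusted p = 0.096). In myb GA3OX2 stood at 1.43 ± 0.817 CPM and in WT at 6.59 ± 2.296. The aliphatic list did not shift among its tested genes, which leave out MAM1, MAM3, CYP79F1 and CYP79F2 (adjusted p = 0.69 in myb and 0.92 in qko). The indolic list did not shift either (adjusted p = 0.05 and 0.36), although CYP81F3 (AT4G37400, log2 fold change 4.20, SE 0.23, adjusted p = 1.9e-16) rose in qko. In total 6437 genes changed in myb and 9163 in qko. With total-count scaling the share that were higher in myb went from 50.3% to 60.6%.

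**Figure D3:**
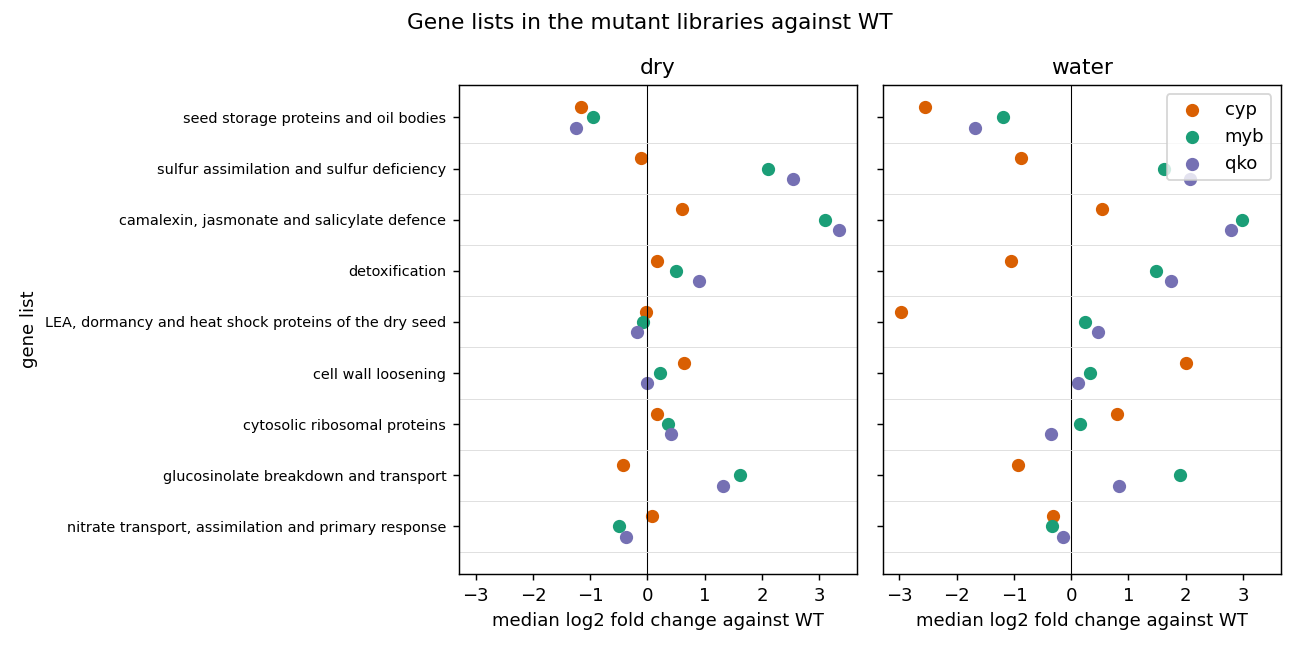
Median log2 fold change against WT of gene lists in dry seeds and in seeds imbibed in water (points), for libraries labelled cyp, myb and qko. The LEA, dormancy and heat shock list lay at -2.97 in cyp in water and the sulfur list at 2.08 in qko.

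**Figure D4:**
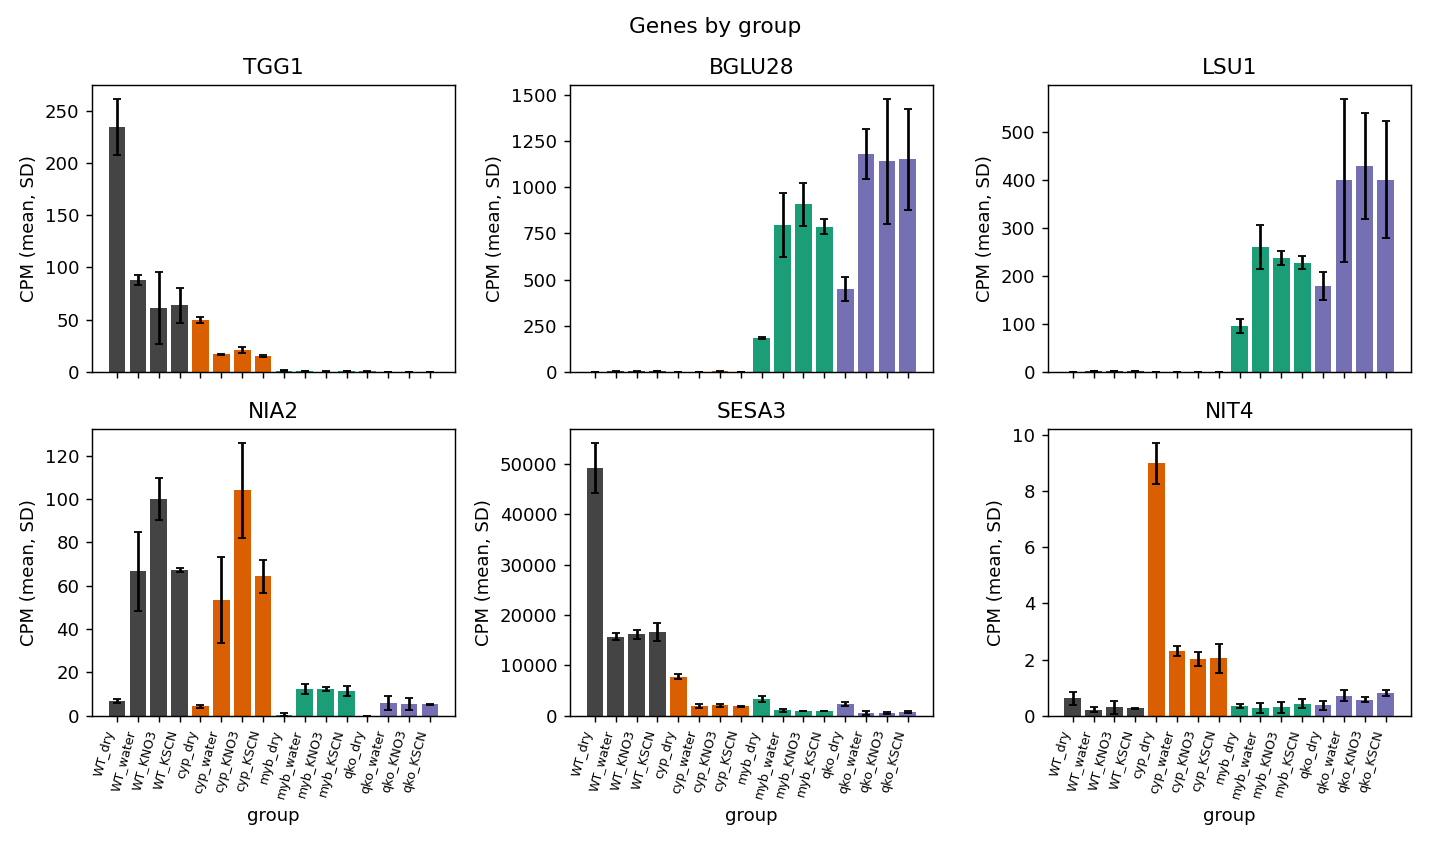
Mean CPM of 6 genes in each of the 16 groups, with the SD between libraries as error bars. TGG1 stood at 87.7 CPM in WT in water and 0.834 in myb, and LSU1 at 1.25 and 260.2.

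Whether the mutants imbibed differently from WT was tested as the difference between their changes from dry to water. In the libraries labelled cyp the LEA, dormancy and heat shock genes changed more downwards than in WT. All 12 LEA, dormancy and heat shock genes and 18 of 29 ABA genes changed less upwards or more downwards than in WT (adjusted over the list alone, 12 and 20). HSP21, a plastid heat shock protein gene, rose in WT and fell in cyp: HSP21 (AT4G27670, log2 difference -7.37, SE 0.69, adjusted p = 1.5e-10). AT1G59860 (log2 difference -5.70, SE 0.47, adjusted p = 9.3e-12), a small heat shock protein gene, rose in WT. DRT112 (AT1G20340, log2 difference 4.32, SE 0.84, adjusted p = 1.1e-04), which encodes plastocyanin, rose in cyp and fell in WT. The LEA list differed with a median log2 fold change -2.85, adjusted p = 5.1e-11, and adjusted p = 0.092 with an estimated correlation, and the ribosomal protein list with a median log2 fold change 0.65, adjusted p = 2.1e-06, and adjusted p = 0.32 with an estimated correlation. In total 6354 genes responded differently in cyp, 2227 with a higher and 4127 with a lower change.

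Fewer genes responded differently in the libraries labelled myb and qko. DIN10, a raffinose synthase gene of starved tissue, rose in WT: DIN10 (AT5G20250, log2 difference -6.25, SE 1.16, adjusted p = 3.6e-04) in myb, and -8.03 (SE 1.11) in qko. GT72B1 (AT4G01070, log2 difference 2.99, SE 0.36, adjusted p = 3.9e-07), a glucosyltransferase gene for foreign compounds, rose in myb and fell in WT. In qko 9 of 11 lipid mobilisation genes changed less upwards or more downwards than in WT (median log2 fold change -0.70, adjusted p = 9.1e-05, and adjusted p = 0.49 with an estimated correlation), as did 10 of 25 gibberellin genes (median log2 fold change -0.58, adjusted p = 9.1e-05, and adjusted p = 0.17 with an estimated correlation). Adjusted over the list alone these counts were 9 and 10. The gibberellin median from dry to water in qko was 1.29, and 0.413 with bounds, while no bound was computed for the difference. In total 2083 genes responded differently in myb and 5013 in qko. Without replicate 5 of dry myb the myb count was 1113. With total-count scaling the share with a higher change in myb went from 46.7% to 34.5%.

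Whether nitrate acts differently in the mutants was asked by comparing KNO3 with water in each. Most genes of the nitrate list rose in the libraries labelled cyp, in a comparison whose count of genes changed with the libraries used. Of the nitrate list, 16 of 25 rose, 0 fell and 9 did not pass (adjusted over the list alone, 20 rose and 1 fell). RFNR2 (AT1G30510, log2 fold change 1.91, SE 0.33, adjusted p = 6.4e-04) and NIA1 (log2 fold change 1.77, SE 0.31, adjusted p = 8.1e-04) rose with NIR1, the nitrite reductase gene, at 1067 ± 553 CPM in KNO3 and 296 ± 124 in water (n = 3 each). UPM1 (AT5G40850, log2 fold change 0.88, SE 0.09, adjusted p = 2.3e-07) rose too, and so did WOX2 (AT5G59340, log2 fold change 1.86, SE 0.24, adjusted p = 2.9e-05), an embryo homeobox gene. GPT2 (AT1G61800, log2 fold change -1.59, SE 0.26, adjusted p = 5.1e-04), a plastid glucose phosphate carrier gene, fell. The list gave a median log2 fold change 0.88, adjusted p = 1.9e-25, and adjusted p = 0.0045 with an estimated correlation. In total 358 genes changed, 206 higher and 152 lower. The share that were higher went from 57.5% to 46.9% with total-count scaling. The count was 93, 878 and 88 without replicate 7, 8 or 9 of cyp in water, and 2609, 95 and 72 without replicate 6, 7 or 8 of cyp in KNO3. It was 552 by DESeq2, and 0 when the model held only the 6 libraries compared.

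In the libraries labelled myb and qko KNO3 changed 0 genes by edgeR. In myb 291 genes had an unadjusted p under 0.05 and DESeq2 called 0, and in qko these were 556 and 1. In the imbibed qko libraries, of which replicate 7 lay apart, a replicate block within them gave 14 changed genes. UPM1 stood at 175 ± 1.43 CPM in KNO3 and 176 ± 1.95 in water in myb (n = 2 and 3), and at 202 ± 17.9 and 203 ± 14.7 in qko. The nitrate list did not shift in either (median 0.02, adjusted p = 0.51 in myb, and median 0.05, adjusted p = 0.65 in qko). Against WT the response of the list was higher in cyp (median log2 fold change 0.53, adjusted p = 1.2e-12, and adjusted p = 0.13 with an estimated correlation). It was lower in myb (median log2 fold change -0.16, adjusted p = 0.0052, and adjusted p = 0.79 with an estimated correlation) and in qko (median log2 fold change -0.21, adjusted p = 6.4e-04, and adjusted p = 0.55 with an estimated correlation). The difference in myb was lost without replicate 8 of WT in water (adjusted p = 0.11) or replicate 6 of WT in KNO3 (adjusted p = 0.098), and that in qko without replicate 7 of qko in KNO3 (adjusted p = 0.063). No single gene responded differently by edgeR, with 1059, 347 and 530 genes at an unadjusted p under 0.05 in cyp, myb and qko and 9, 0 and 1 by DESeq2. In cyp 11 genes passed without replicate 8 of cyp in water and 296 without replicate 6 of cyp in KNO3.

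**Figure D5:**
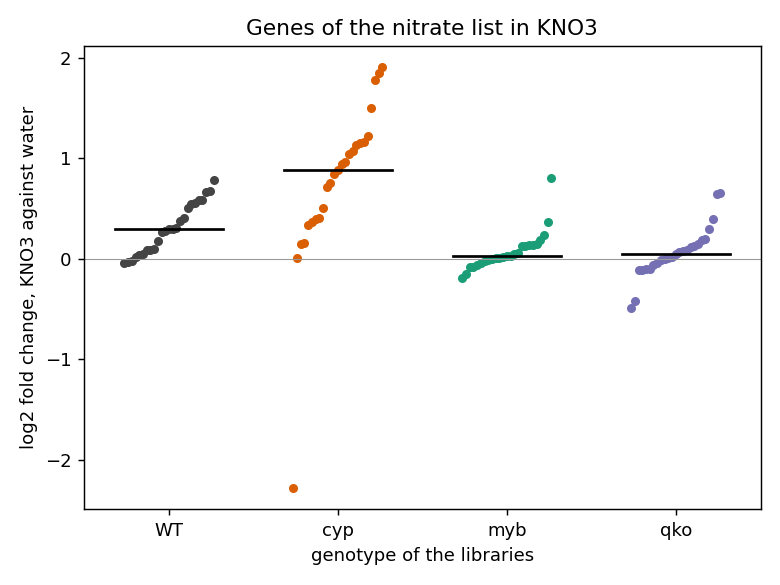
Log2 fold change between KNO3 and water of each tested gene of the nitrate list (points) by the genotype label of the libraries, with the median of the list as a bar. The median was 0.29 in WT, 0.88 in cyp, 0.02 in myb and 0.05 in qko.

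Whether thiocyanate acts differently in the mutants was asked by comparing KSCN with water in each. No ribosomal protein gene passed over all genes tested, but their list shifted down at the preset correlation and not with an estimated one. It gave a median log2 fold change -0.18, adjusted p = 1.2e-06, and adjusted p = 0.52 with an estimated correlation in cyp, a median log2 fold change -0.36, adjusted p = 1.6e-12, and adjusted p = 0.64 with an estimated correlation in myb and a median log2 fold change -0.22, adjusted p = 8.7e-08, and adjusted p = 0.49 with an estimated correlation in qko. In cyp the direction against other genes reversed (median -0.03) without replicate 8 of cyp in KSCN. In myb 17 of 20 fell adjusted over the list alone and 0 over all genes tested. RPL27AC (AT1G70600) stood at 373 ± 22.5 CPM in KSCN and 473 ± 41.0 in water in myb (adjusted p = 0.36), and at 276 ± 10.6 and 329 ± 17.1 in qko. By edgeR 0 genes changed in cyp, myb and qko, with 339, 2270 and 742 at an unadjusted p under 0.05 and 0 by DESeq2 in each. With a replicate block within the imbibed qko libraries, of which replicate 7 lay apart, 42 genes changed in qko. In myb 189 genes passed when the model held only the groups compared, and 180 passed without replicate 9 of myb in water. No gene responded differently from WT by edgeR, with 205, 709 and 306 at an unadjusted p under 0.05 and 1, 0 and 0 by DESeq2.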

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

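The tests of mixed seeds, of scaling, of shared reads and of exchanged labels were chosen after the results were seen. The results given here stand out as differences between groups: the response of a mutant to imbibition, nitrate or thiocyanate differed from that of WT by a test of the difference itself. For KNO3 and KSCN this holds for lists alone and at the preset correlation alone, with 0 single genes by edgeR, and for most of these lists the call was lost without 1 library.

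From dry seeds to seeds in water, 6354 genes responded differently in the libraries labelled cyp, 2083 in those labelled myb and 5013 in those labelled qko. Single genes with the largest differences (log2, mutant minus WT) were DRT112 (4.32), HSP21 (-7.37) and AT1G59860 (-5.70) in cyp. In myb they were GT72B1 (2.99), AT3G19615 (2.86) and DIN10 (-6.25), and in qko DIN10 (-8.03). The other 11 genes had a group under 3 counts per library, so their size is uncertain. They were BGLU23 (10.24), AT5G51560 (5.37) and ATMG00220 (-8.94) in cyp, AT5G22140 (6.68), AT3G24420 (-6.17) and sks13 (-5.60) in myb, and AT4G31360 (6.77), ALN (5.35), AT5G22140 (5.04), AT2G26450 (-6.19) and FAR1 (-5.67) in qko. Of these, AT5G51560, ALN, AT2G26450 and AT5G22140 in both mutants changed their call under another setting.

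Lists of genes differed too, all at the preset correlation and none with an estimated one. In cyp the list medians of these differences were -2.85 for LEA, dormancy and heat shock, -1.36 for storage, -1.31 for ABA, -0.97 for detoxification and -0.87 for sulfur. They were 2.29 for the 4 photosynthesis markers, 1.39 for cell wall loosening, 1.03 for auxin, 0.65 for ribosomal proteins, 0.42 for ribosome biogenesis and 0.36 for gibberellin. In myb the median was 0.54 for detoxification. In qko they were -0.82 for cyanide and thiocyanate, -0.70 for lipid mobilisation, -0.64 for ribosomal proteins, -0.58 for gibberellin and 0.63 for detoxification. With KNO3 the nitrate list differed by 0.53 in cyp, -0.16 in myb and -0.21 in qko. Others with KNO3 in cyp were ammonium and asparagine (0.30), glucosinolate breakdown and transport (0.23), lipid mobilisation (0.20) and ribosomal proteins (-0.24), and in qko auxin (0.28) and ribosomal proteins (0.14). With KSCN they were the nitrate list (0.19) and LEA, dormancy and heat shock (-0.27) in cyp and ribosomal proteins (-0.26) in myb. In qko they were storage (0.19), ribosome biogenesis (-0.19) and ribosomal proteins (-0.11). Of these 32 list differences 16 lost their call without 1 library. They were detoxification in cyp and myb and the cyanide list in qko for imbibition, and all those given for KNO3 and KSCN except the nitrate list with KNO3 in cyp and the ribosomal list with KSCN in myb.

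The imbibed libraries of qko replicate 7 lay apart from replicates 4 and 6 of their own groups, with a mitochondrial share of 0.170% in water, 0.282% in KNO3 and 0.217% in KSCN. Lower depth is argued against: with all imbibed qko libraries thinned to the total of the shallowest (18097331 counts), replicate 7 still differed from the others in at least 2.18 times as many genes as they differed from each other. A share of WT or cyp seeds is argued against too, since genes at least 8 times higher there than in qko rose in replicate 7, over replicates 4 and 6, by a median share of at most 0.00508 of the way to their level there. A length or GC trend may be a part of the cause: taking both trends out left 45.7% of the genes apart in KNO3, the lowest of the 3 treatments, and the difference went with transcript length (rho -0.58 in KNO3). Seeds of myb mixed in cannot be told apart from the other causes, because only 1 gene could be used and its highest share was 0.128. A difference between seed lots was not tested. In dry qko seeds replicate 7 did not stand apart. Its mean chi-square per gene was 7.19 and 13.4 against replicates 4 and 6, and 10.7 between those. The labels do not say whether dry and imbibed libraries of the same number share a seed lot.

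The water libraries labelled cyp had LEA, dormancy and heat shock genes below WT and ribosomal protein genes above it, as if further from the dry state. Scaling set by a few abundant transcripts is argued against as the whole cause, because 1 factor per library moves all lists alike and cannot make the gap of 3.78 (log2) between these list medians. Whether these seeds are further along the same course cannot be told apart from another difference: across genes, which are not independent replicates, the difference from WT went with the mean change from dry to water in myb and qko at a correlation of 0.292 (0.369 by rank). Values over 0.3 were asked for and only the rank value passed, and in dry seeds these were 0.0825 and 0.141. Lists went both ways: storage, ABA, gibberellin and cell wall genes differed in cyp from WT in the direction of the WT medians from dry to water. Of these lists, ABA and gibberellin did not shift against other genes in WT. The detoxification and sulfur lists went the other way. Their medians from dry to water in WT were 1.33 and 0.87, though neither list shifted there, and in water they lay below WT in cyp. With bounds for genes with a group at 0 counts, the sulfur median in WT was 0.56. Seed age, harvest and maturity of the seed lots were not tested, and a candidate explanation is that the lots differ in these.

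CYP79B2 and CYP79B3 were higher in the libraries labelled cyp than in WT. Reads shared between the copies are argued against, since the sum of both copies stood at 3.82 ± 0.594 CPM in cyp and 0.221 ± 0.0835 in WT in water, a ratio of 17.3 with 16 counts in WT. In dry seeds the ratio of 12.5 is of uncertain size, because WT held 8 counts, under 3 per library. Labels of cyp exchanged with another genotype cannot be told apart from a transcript that remains in the mutant: 0 of the 8 other mutant groups had a mean of CYP79B3 below that of WT, CYP79B2 was below WT in qko in dry seeds, water and KSCN but with both under 3 counts per library, and an insertion can leave a locus transcribed. Which allele was used was not tested.

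Other splits of the libraries were counted for each comparison with 3 libraries in both groups, in models of those libraries alone. With 10 splits of 6 libraries the splits are too few for a share under 0.05, and the values are these. For water against dry 1 split gave as many genes as the real one in WT (12834 genes, 0 in the highest other split), 1 in cyp (14224 and 0) and 1 in qko (11008 and 0). For KNO3 against water these were 1 in WT (1 and 0), 10 in cyp (0 and 1) and 10 in qko (0 and 0). For KSCN against water they were 10 in WT (0 and 15), 1 in myb (189 and 0) and 10 in qko (0 and 0). For mutants against WT in dry seeds they were 1 in cyp (8044 and 0) and 1 in qko (10048 and 0), and in water 1 in cyp (11813 and 0), 1 in myb (6832 and 0) and 1 in qko (7271 and 0).

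For the differences in response, 100 of 200 splits were drawn that exchange libraries between genotypes within a treatment. These splits carry the genotype difference itself. For water against dry 2 of 100 splits gave as many genes as the real one in cyp (8085 genes, 11542 in the highest other split) and 2 of 100 in qko (5041 and 10078). This share under 0.05 does not measure chance in the response, because the genotype difference enters the counts of the other splits. For KNO3 against water all 100 did in cyp (0 and 12738) and all 100 in qko (0 and 9655). For KSCN against water all 100 did in myb (0 and 9915) and all 100 in qko (0 and 10696). With a real count of 0 every split gives as many genes, so for these 4 too the splits say nothing about chance. Splits that call many genes where the real one calls 0 point to a structure of the samples, here the genotype difference that an uneven exchange leaves in a treatment.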

How the results depend on the processing

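Total-count scaling, the sets without imbibed cyp replicate 8 or imbibed qko replicate 7, and the block within imbibed qko libraries were chosen after seeing the data. The other alternatives were planned. Counts of genes stayed within 1.5 times their value with size factors of the DESeq2 type and without a filter, for all 27 comparisons. With the exceptions below, they did so under the other alternatives too. The number of list shifts in the main comparisons was 44, and ranged from 41 to 54 with 1 library left out.

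For KNO3 against water in WT the count of 0 became 2 with the replicate block, 2 with total-count scaling, 2 by DESeq2 and 1 with only the groups compared, and ranged from 0 to 2 with 1 library left out. In cyp the count of 358 became 531 with the replicate block, 552 by DESeq2, 0 with only the groups compared and 173 without imbibed cyp replicate 8, and ranged from 72 to 2609 with 1 library left out. In qko it went from 0 to 1 by DESeq2 and to 14 with the replicate block within imbibed qko libraries. For KSCN against water the replicate block gave 1 gene in cyp and 1 in myb. In myb only the groups compared gave 189, and leaving out 1 library gave 0 to 180. In qko the replicate block within imbibed qko libraries gave 42.

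For cyp against WT in dry seeds the count of 5319 became 9211 with total-count scaling and 8044 with only the groups compared. The count of 2083 genes with another response to imbibition in myb ranged from 1113 to 2267 with 1 library left out. For another response to KNO3 in cyp the count of 0 became 9 by DESeq2 and 2 without imbibed cyp replicate 8, and ranged from 0 to 296 with 1 library left out. DESeq2 gave 1 gene for KNO3 in qko and 1 for KSCN in cyp. For all of these the cause was not tested.

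The direction of a list against other genes reversed in 10 of 4389 values with 1 library left out and in 2 of 147 without imbibed qko replicate 7. Among the 4389 values, 109 lost the call and 109 gained it, in 108 list results. The ranges of medians with 1 library left out were these, with the reversal at the end named. With KSCN in cyp they were -0.343 to -0.0288 for ribosomal proteins, -0.0773 to 0.216 for ABA (-0.111 to 0.136 as a difference from WT) and -0.409 to 0.0333 for auxin, reversed without replicate 8 of cyp in KSCN. They were -0.427 to 0.0248 for LEA, dormancy and heat shock (difference -0.519 to -0.00861), reversed without replicate 6 of cyp in KSCN. With KNO3 in qko they were -0.0489 to 0.203 for ribosomal proteins (difference -0.0311 to 0.236) and -0.269 to 0.339 for LEA, dormancy and heat shock, reversed without replicate 7 of qko in KNO3. They were -0.142 to 0.167 for lipid mobilisation, reversed without replicate 7 of qko in water. Without imbibed qko replicate 7 the ribosomal list became -0.0362 (difference 0.0119). A median can keep its sign where the direction against other genes turns. Over all comparisons the list calls lost and gained were 14 and 16 without a filter and 9 and 16 with the replicate block. They were 13 and 12 with total-count scaling, 15 and 13 with only the groups compared, and 0 and 2 with size factors of the DESeq2 type.

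IIL1 in dry cyp against WT became 0.0842 (log2) and MYC3 in water against dry seeds in qko became 0.363 with total-count scaling. The cause was not tested. Of 5080 values of named genes with 1 library left out, 4924 kept their side of the threshold, 146 fell behind it and 10 passed it. Where this left 1 library in a group, that library is assumed to vary like the other groups. Depth limits genes of few counts, such as MYB28 and MYB29.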
